A study of Mus musculus with 2 samples.

How the data were processed

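H3K36me3 chromatin immunoprecipitation and sequencing data from mouse embryonic day 15.5 liver were used, from 2 biological replicates of a single group, each a pool of embryos of both sexes. The replicate numbers come from the labels. Per the labels, the coordinates are on mm10 and a control experiment exists for these libraries. The aligner, the peak caller, their versions and the calling threshold are not given in the sources used here. The deposited lists were, per the labels: the peaks of replicate 1, the peaks of replicate 2, the peaks of the alignments of both replicates pooled, and the replicated peaks, which were derived from the other lists by a rule not given in the sources used here. All 99568 replicated peaks were found unchanged in the pooled list of 165497, and 89400 of them (89.8%) overlapped a peak of both replicates. The pooled peaks left out had a lower enrichment (median 2.24 against 3.18).

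Each deposited peak carries an enrichment ratio and a -log10 q-value that the authors' caller gave it. What the enrichment ratio of the authors was computed against is not stated in the files. These values were used only within a list, to describe, rank or filter peaks and, in the closing tests, to compare the highest enrichment between groups of genes. The deposited lists had already been thresholded, and 99.5% of the replicated peaks had a -log10 q-value of at least 2. Read numbers per library are not part of the lists, so depth is unknown, and the precision of a value rests on the spread between the 2 replicate lists. A weaker library or a stricter threshold would shorten the coverage of weakly marked genes first.

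Genes, exons and transcription starts came from GENCODE release M21 on the mm10 (GRCm38) assembly, and chromosome lengths and unsequenced gaps from the reference sequence of the same assembly. No peak or gene lay past the end of its chromosome. Peaks on chromosomes 1 to 19, X and Y were analysed, and those on scaffolds outside them were set aside. For each gene the share of the body, from annotated start to end over all transcripts, that lay under peaks was computed. A gene was called marked where replicated peaks covered at least 10% of the body. The main result used the replicated peaks, and each replicate list gave a value of its own, from which mean and SD were taken (n = 2). Shares of genes carry Wilson 95% intervals, which cover the number of genes only. Peaks of the replicates were compared by an overlap of at least 1 base and by the shared covered bases. For comparison, 100 random placements moved each peak singly to a place on its chromosome outside gaps. They do not keep the concentration of peaks in genes. The gene body profile used 10 equal bins over marked genes of 10 kb or more and compared the mean of the last 3 bins with that of the first 3. Flanking coverage was measured in 1 kb steps over the marked genes of that length with no other protein-coding gene in the 10 kb on that side.

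The group, the tests, the alternatives, the rule for named genes and 19 gene lists were fixed before the data were examined. The lists were erythroid, heme synthesis and iron uptake, fetal hepatocyte, adult hepatocyte, cholangiocyte, megakaryocyte and platelet, myeloid and macrophage, blood stem and progenitor, lymphoid, endothelial, stellate and mesenchymal, neuronal, skeletal and heart muscle, male germline, widely expressed, cell cycle, H3K36 methylation, polycomb developmental and imprinted genes. Of 486 symbols, 483 matched a gene, 2 were second symbols of a member and 1 had no match. The share of marked members was compared between lists in 6 contrasts by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment and a threshold of 0.05. By plan, each list's median coverage was placed among 10000 random lists of protein-coding genes matched on deciles of gene length. Mean coverage was also placed among them and was not part of that plan. Genes were named by a fixed rule: the 10 protein-coding genes of 10 kb or more with the largest mean coverage over the replicates; the 2 members of each list with the largest and the 1 with the smallest coverage, ties in alphabetical order; Alb, Afp, Hba-a1, Hbb-bs, Gata1 and Setd2 always; the 3 genes of 10 kb or more with the largest difference in each direction between the replicates among genes marked in at least 1; and the genes holding the 5 replicated peaks of highest enrichment. Further members of lists, chosen after their values were seen, are named as examples or as the exceptions of a list.

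The computation was tested on simulated peaks: 400 of 400 genes with planted peaks fell on the right side of the threshold, none of 10591 genes without planted peaks was called, and the observed overlap of random lists was 18.6% where 18.1% was expected. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, with bedtools 2.31.1 for reciprocal overlaps. The alternatives were other rules of overlap, a minimum -log10 q-value of 2, the 50% of peaks of higher enrichment in each list, joining of peaks less than 1 kb apart, the pooled list, each replicate alone, a marked gene at 25% or at any covered base, genes of 2 kb or more, all annotated genes, and other bins and lengths for the profile. Genes that overlap no other protein-coding gene were added as an alternative after the data had been seen.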

Results

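Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down in gene bodies behind elongating RNA polymerase II, was profiled by chromatin immunoprecipitation and sequencing in the liver of mouse embryos at embryonic day 15.5. At this age the liver is both the main site of red cell production and a growing hepatic organ. A single group was present, with 2 biological replicates. Replicate 1 was made from the pooled livers of 78 embryos and replicate 2 from those of 62, both of strain B6NCrl with male and female embryos mixed. The authors' peak lists held 155517 peaks for replicate 1 and 168617 for replicate 2, and 99568 peaks in the list of replicated peaks, which covered 111 Mb or 4.19% of the assembled genome. Peak lists carry no read numbers, so the sequencing depth behind each list is unknown, and no interval based on reads is given. Unless stated otherwise, gene values below are the share of a gene body under replicated peaks, and values with an error are the mean ± SD of the 2 replicate lists (n = 2).

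The first comparison asked how far the 2 pools of livers shared their H3K36me3 peaks. Slc4a1, the anion exchanger of the red cell membrane, was covered over 87.2% ± 0.297 of its body, and Top2a, the topoisomerase of dividing cells, over 95.2% ± 0.149. Across the genome, 73.1% of the peaks of replicate 1 overlapped a peak of replicate 2 by at least 1 base, and 73.7% of those of replicate 2 overlapped a peak of replicate 1 (mean 73.4% ± 0.444, n = 2). The highest mean in 100 random placements of the peaks within their chromosomes was 7.55%. Shared bases made up 60.6% of all bases covered in either list, against at most 2.32% after random placement. Peaks of replicate 1 without a partner were narrower (median 240 bp against 464 bp) and had a lower enrichment as given by the authors (median 2.72 against 3.34). When an overlap of at least 50% of both peaks was required, the mean shared percentage was 41.3%.

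H3K36me3 lay almost entirely within protein-coding genes. Gene bodies held 95.2% of the bases under replicated peaks (replicates 95.1% ± 0.105, n = 2), although they make up 39.3% of the chromosomes, and 100 random placements gave 41.3% to 42.6%. Exons of protein-coding genes held 22.6% of the peak bases and 3.63% of the genome, a 6.22-fold excess, and introns held 72.6% against 35.7%. Promoters, taken as the 1 kb on each side of a transcription start, held 0.441% of peak bases against 1.56% of the genome, a ratio of 0.282. Sequence outside all annotated genes held 4.05% of peak bases and 53.9% of the genome. Each of these departures was many times the SD between replicates, which was at most 0.384 percentage points in any class. Within marked genes, 59.8% of exonic bases and 38.2% of the other bases were covered. Gene length and position along the gene were not held fixed in this comparison.

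Long marked genes carried the mark mainly toward their 3′ ends. In Ank1, the ankyrin of the red cell skeleton (mm10 chromosome 8, 22974844 to 23150497, plus strand), 62.8% of the body was covered, and in Setd2, which encodes the enzyme that trimethylates H3K36, 62.5% (replicates 57.2% ± 3.95). Over the 5574 marked protein-coding genes of 10 kb or more, coverage rose from 9.48% in the bin at the transcription start to 65.1% in the ninth of 10 equal bins and was 62.0% in the last. The mean of the last 3 bins was 2.32 times that of the first 3 (63.1% against 27.2%), and the ratio in the replicate lists was 2.33 ± 0.0475 (n = 2). In 4750 of these genes (85.2%, Wilson 95% interval 84.3 to 86.1), coverage was higher on the 3′ side of the midpoint of the body than on the 5′ side. Beyond the annotated end, coverage was 40.1% in the first kb, 22.4% at 2 kb, 10.7% at 3 kb and 5.71% at 4 kb among 2064 genes with no other protein-coding gene in the 10 kb downstream, while the first kb upstream of the start held 0.182% among 2813 genes. The last bin of 10 against the first gave a ratio of 6.54.

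**Figure D1:**
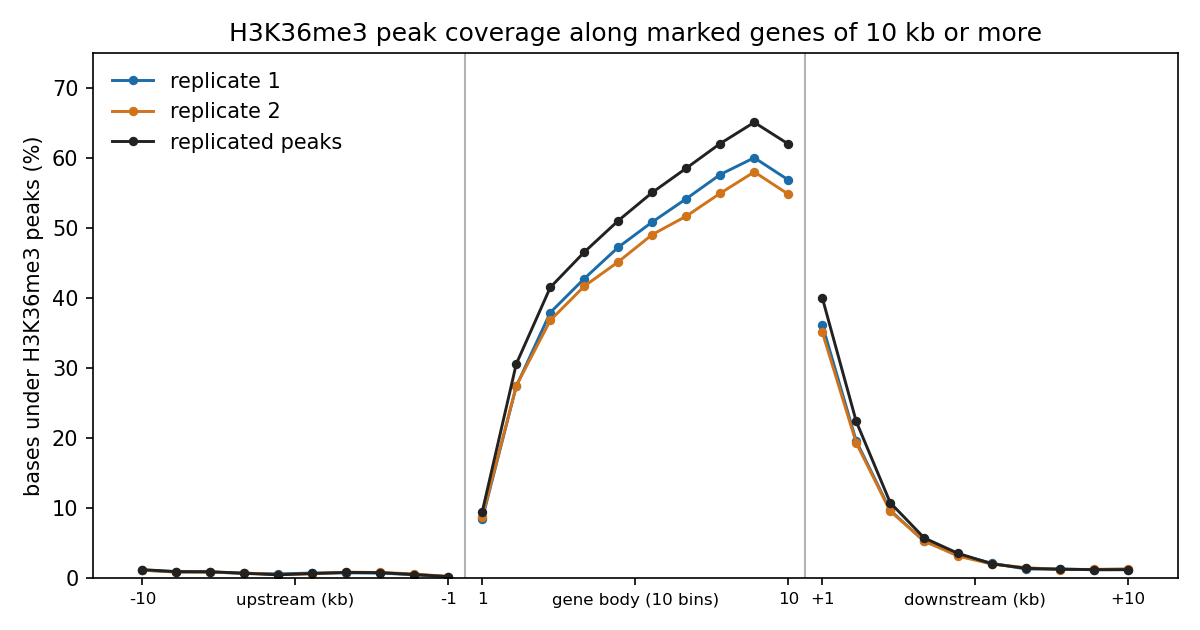
Share of bases under H3K36me3 peaks (vertical axis, percent) in each kb upstream, each of 10 equal bins of the gene body and each kb downstream of marked protein-coding genes of 10 kb or more (horizontal axis), for replicate 1, replicate 2 and the replicated peaks. Coverage climbs from 9.48% in the bin at the start to 65.1% in the ninth bin of the replicated peaks and has fallen to 5.71% at 4 kb past the gene end.

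Among protein-coding genes of 10 kb or more, the largest mean coverage belonged to Slc2a1, the glucose transporter GLUT1 (96.2% ± 0.0580), then Top2a (95.2% ± 0.149), Dlgap5, a spindle protein (95.2% ± 0.395), Sf3a1, a splicing factor (94.7% ± 0.997), and Mcm5, a subunit of the replicative helicase (94.3% ± 0.0337). Tut7, Ncapd2, Kpnb1, Sf3b3 and Bub1b completed the leading 10, between 94.2% ± 0.0740 and 92.2% ± 0.747. In all, 7481 of 21938 protein-coding genes (34.1%, Wilson 95% interval 33.5 to 34.7) had at least 10% of the body under replicated peaks and were counted as marked. The replicate lists gave 7382 ± 7.07 marked genes (n = 2). The median marked gene was covered over 48.5% of its body, 3626 genes were covered over at least 50%, and 12152 (55.4%) had no covered base. The marked share was highest at gene lengths of 10 to 50 kb (45.4%), and was 7.49% below 2 kb and 5.21% at 200 kb or more. Of the marked genes, 2367 (31.6%) overlapped another protein-coding gene, whose mark cannot be separated from their own in a peak list.

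The replicated peak of highest enrichment, as given by the authors, spanned 8.65 kb within Tpm1, a tropomyosin gene (mm10 chromosome 9, 67027932 to 67036577), with an enrichment of 16.7. It was followed by peaks in Trim56, a ubiquitin ligase gene (chromosome 5, 137112447 to 137115421, enrichment 16.1), and Ccnf, the cyclin F gene (chromosome 17, 24240609 to 24245660, enrichment 15.5). The next covered the 3′ end of Zfpm1, the GATA1 cofactor FOG1, and ran past it (chromosome 8, 122332673 to 122340463, enrichment 15.4), and the fifth lay in Ank1 (chromosome 8, 23069289 to 23086192, enrichment 15.2). Gm20388, a read-through gene model that spans Zfpm1 and many other genes, also holds the fourth peak and was covered over 15.9% of its length.

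Erythroid genes were among the most heavily marked genes of this tissue. Of 35 erythroid genes, 29 were marked in the replicated list and in each replicate list, with a median coverage of 71.9% (median of the replicates 66.2% ± 1.81, n = 2). Epb42, a membrane skeleton protein (90.1% ± 0.479), and Slc4a1 (87.2% ± 0.297) were highest, followed by the rhesus protein gene Rhd (85.7% ± 2.17) and the transferrin receptor Tfrc (85.2% ± 1.68). The transcription factor gene Gata1 was covered over 23.9% ± 1.59 of its body. The 6 unmarked members were the globin genes: Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Hbb-bh1 and Hbb-y had no base under a replicated peak, and Hbb-bt alone had a trace in the replicate lists (0.339% ± 0.480). Their bodies are short, from 0.810 kb to 1.56 kb, and several have a near-identical copy. Heme synthesis and iron uptake genes followed the erythroid list, with 17 of 20 marked (18 in each replicate list) and a median coverage of 57.1%. Abcb10, a mitochondrial transporter needed for heme synthesis (91.4% ± 1.01), and the biliverdin reductase gene Blvrb (87.2% ± 0.140) led this list, and Abcb7 on the X chromosome was lowest (0.444% ± 0.193). Both lists had a higher mean coverage than all 10000 random lists of protein-coding genes matched on length.

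Hepatocyte genes carried much less of the mark, including the most abundantly secreted plasma proteins. Alb, the albumin gene (mm10 chromosome 5, 90460897 to 90476602), had no covered base in any list, and Afp, the alpha-fetoprotein gene beside it, had none in the replicated list and 2.53% ± 0.965 in the replicate lists. Of 39 fetal hepatocyte genes, 11 were marked, with a median coverage of 2.74% (replicates 5.15% ± 0.0704, n = 2), and 4 of the 11 overlap another protein-coding gene. The marked share, 28.2%, depended on the setting: it was 48.7% (19 genes) in the pooled list, 56.4% when any covered base counted, and 10.3% with 25% coverage or with the 50% of peaks of higher enrichment. The complement gene C3 (40.8% ± 8.70) and the urea cycle gene Ass1 (32.9% ± 0.577) were highest, the antithrombin gene Serpinc1, which overlaps the marked gene Zbtb37, reached 14.2% ± 0.513, and the fetuin gene Ahsg had no covered base. The mean coverage of this list was 8.32%, and only 0.39% of random lists matched on length had a mean as low, whereas its median lay above 79.7% of the medians of those lists, whose own median was 0. Of 30 adult hepatocyte genes, 4 were marked: the glutamine synthetase gene Glul (73.9% ± 2.27), Oat (51.3% ± 0.127), Slc10a1 (49.98% ± 1.19) and Arg1 (22.4% ± 0.934). Slc10a1 and Arg1 lie 2.68 kb and 1.54 kb from the marked genes Srsf5 and Med23. The other members, among them the cytochrome P450 genes Cyp2e1, Cyp3a11 and Cyp7a1, were unmarked, and Ces3a had no covered base.

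Few markers of the other cell types of the liver were marked. None of 11 cholangiocyte genes, 16 megakaryocyte and platelet genes or 18 lymphoid genes was marked in the replicated list. Hnf1b (1.35% ± 0.856), Gp9 (5.04% ± 7.13) and Cd79b (2.00% ± 2.83) had the highest mean coverage in these lists, and the last 2 had none in the replicated list; Gp9 passed the limit for a marked gene in replicate 2 (10.1%) and in the pooled list (11.3%). Next within their own lists were Jag1 (0.242% ± 0.342), Thbs1 (1.79% ± 0.904) and Tcf7 (0.765% ± 0.150). Of 22 myeloid and macrophage genes only Cd68 was marked (91.4% ± 5.61), and it lies 0.782 kb from the marked translation factor gene Eif4a1, while Csf1r had 6.99% ± 0.592 and Adgre1 had none. Of 18 endothelial genes Stab1 was marked (26.4% ± 2.37), and of 20 stellate and mesenchymal genes Tagln (28.8% ± 1.76); both overlap another protein-coding gene. A second member of each list, Eng (9.04% ± 2.72) and Ecm1 (16.1% ± 15.9), passed the limit in replicate 2 (11.0% and 27.3%) and in the pooled list (19.2% and 31.0%), but not in replicate 1 or the replicated list. Of 16 blood stem and progenitor genes, Lyl1 (61.2% ± 2.82) and Myb (18.6% ± 1.18) were marked, and 8 had no covered base. Lyl1 overlaps Nfix and lies 1.65 kb from the marked gene Trmt1. Runx1 (9.37% ± 1.35) and Kit (6.81% ± 0.767) held 27 and 8 replicated peaks but were below the limit in the replicated list. Runx1 passed it in replicate 2 (10.3%), and both genes passed it in the pooled list (17.97% and 12.95%). The mean coverage of the blood stem and progenitor list under replicated peaks, 6.95%, was not unusual for its gene lengths, as 12.0% of random lists had a mean as low. Cftr, Gp1ba, Bcl11b, Cldn5, Acta2 and Angpt1, among the lowest members of their lists, had no covered base. Genes of other tissues had essentially no coverage: none of 30 neuronal genes, 25 skeletal and heart muscle genes, 22 male germline genes or 31 polycomb developmental genes was marked. The highest mean coverage in these lists was 0.990% ± 0.794 in Dazl, a germ cell gene. Highest in the muscle list were Actn3 (0.752% ± 1.06) and Neb (0.399% ± 0.0140), and in the neuronal list Kcnq2 (0.149% ± 0.211) and Rbfox3 (0.0306% ± 0.0432). Crem followed Dazl in the germline list (0.342% ± 0.148), while Camk2a, Acta1 and Acr had no covered base. The polycomb developmental genes, among them Barhl1 and Dlx5, had no covered base in the replicate lists.

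Members of the cell cycle and widely expressed lists were marked nearly without exception. Of 32 cell cycle genes 31 were marked, with a median coverage of 86.6% (replicates 84.6% ± 0.861, n = 2), the highest of the 19 lists. Top2a and Mcm5 led this list, and Pola1, a DNA polymerase subunit gene on the X chromosome, was the unmarked member (6.73% ± 0.665). Of 32 widely expressed genes 31 were marked, with a median of 65.9%. The chaperonin gene Cct2 (87.6% ± 1.30) and the elongation factor gene Eef2 (87.3% ± 2.96) were highest, and the polyubiquitin gene Ubb was unmarked in the replicated list (8.76% ± 6.37). Of 28 genes for enzymes and readers of H3K36 methylation 23 were marked, among them Glyr1 (89.4% ± 2.15), the demethylase gene Kdm4a (85.9% ± 2.32) and Setd2, whereas the DNA methyltransferase gene Dnmt3b had 1.79% ± 1.02. Of 38 imprinted genes 11 were marked. H13 (65.7% ± 0.738) and Nespas, which overlaps Gnas (45.8% ± 3.11), were highest, and Igf2, H19 and Ascl2 had no covered base.

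**Figure D2:**
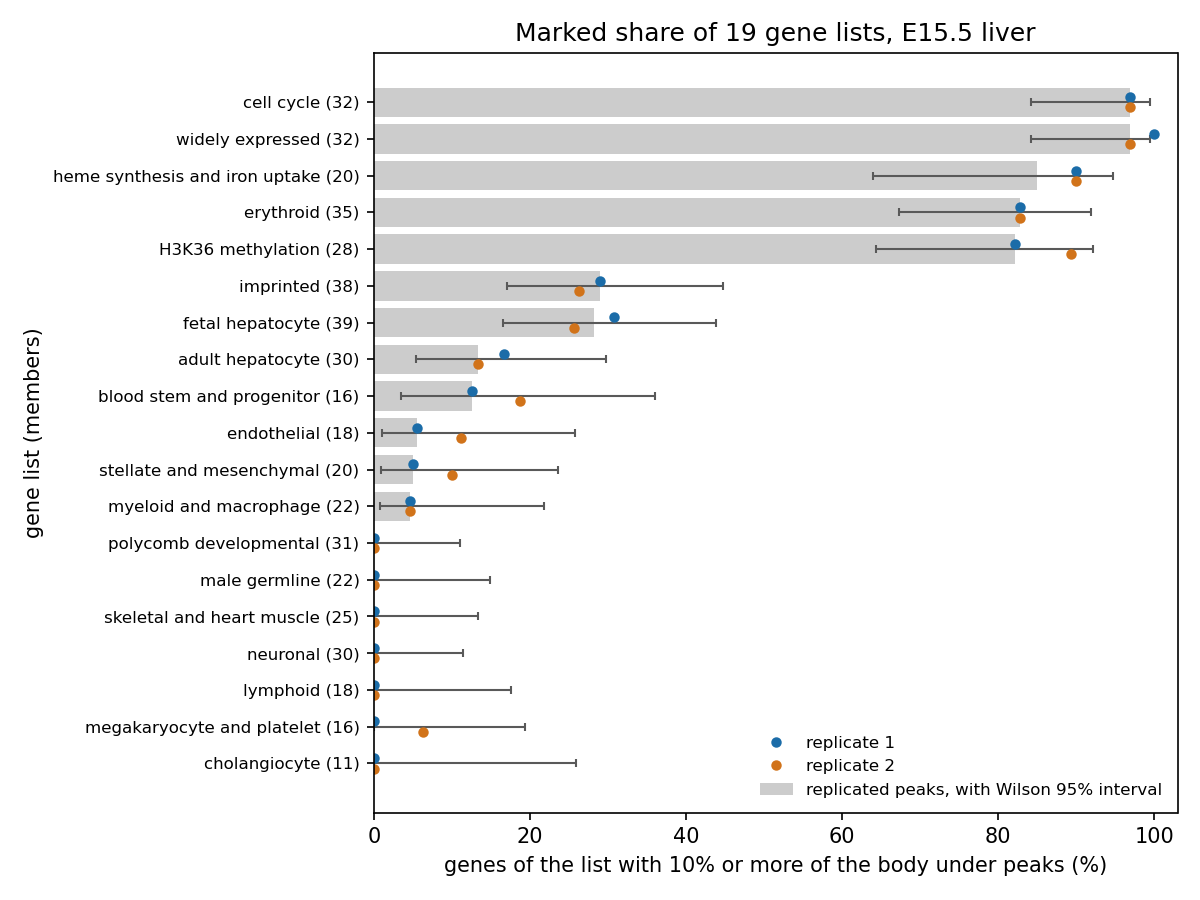
Share of each gene list that was marked (horizontal axis, percent of members) in the replicated peaks (bars, with Wilson 95% intervals over genes) and in each replicate list (points), with the number of members after each list name on the vertical axis. The bars of the cell cycle, widely expressed, heme, erythroid and H3K36 methylation lists all lie above 80%, and every other list lies below 30%.

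The lists were then compared by the share of members marked. Erythroid genes exceeded neuronal genes by 82.9 percentage points (29 of 35 against 0 of 30, Fisher's exact test, adjusted p = 1.31e-12), and widely expressed genes exceeded neuronal genes by 96.9 points (adjusted p = 4.13e-16) and polycomb developmental genes by 96.9 points (adjusted p = 2.16e-16). Erythroid genes exceeded fetal hepatocyte genes by 54.7 points (29 of 35 against 11 of 39, Fisher's exact test, adjusted p = 3.63e-06), and fetal hepatocyte genes exceeded neuronal genes by 28.2 points (adjusted p = 0.00191). The difference between fetal and adult hepatocyte genes (11 of 39 against 4 of 30, 14.9 points) did not pass Fisher's exact test (adjusted p = 0.156). All are two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 6 contrasts. Genes are not replicates of the tissue, so these p-values describe these libraries. The tests did not match genes on length. Median length was 14.1 kb in the fetal hepatocyte list and 99.4 kb in the neuronal list. Random lists matched to them on length were 37.7% and 24.8% marked, so length was not separated from contrasts with the neuronal list. With at least 25% coverage required of a marked gene, or with only the 50% of peaks of higher enrichment, the excess of fetal hepatocyte over neuronal genes was 10.3 points and no longer passed the exact test (adjusted p = 0.152). The fetal to adult hepatocyte difference was 28.7 points in the pooled list (exact test, adjusted p = 0.0223) and -3.08 points at 25% coverage (adjusted p = 0.720). Its size and test result thus depended on the setting, and its direction turned in 1 of 10 settings.

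X-linked genes were marked much less often than autosomal genes. On X, 122 of 948 protein-coding genes were marked (12.9%, Wilson 95% interval 10.9 to 15.2), against 7359 of 20807 on the autosomes (35.4%, interval 34.7 to 36.02). The X share was 11.7% ± 0.522 in the replicate lists (n = 2), and the autosomal share 34.9% ± 0.0578. Single autosomes ranged from 26.7% on chromosome 14 to 42.9% on chromosome 8. Marked X genes were also less covered, with a median of 31.3% against 49.0%. Gata1, the least covered of the marked erythroid genes, and Abcb7 and Pola1, unmarked members of heavily marked lists, lie on X. Abcb7 and Pola1 are also long, at 133 kb and 327 kb, and Pola1 held 32 replicated peaks. Of all protein-coding genes, 34.1% were marked at 50 to 200 kb and 5.21% at 200 kb or more, so length was not separated from X in these 2 genes. Autosomes hold other members of heavily marked lists that were unmarked in the replicated list, among them Hmox1, Hmox2, Ubb, Dnmt3b and the globin genes. Of these, Hmox1 passed the limit in replicate 1 (11.8%), replicate 2 (10.6%) and the pooled list (15.6%). Ubb passed it in replicate 1 (13.3%) and Hmox2 in the pooled list (10.1%). The X-linked heme synthesis gene Alas2 was covered over 65.8% ± 3.51. None of 183 genes on Y was marked. The X share was 8.44% when 25% coverage was required, 7.81% with the 50% of peaks of higher enrichment and 21.1% when any covered base counted, and it stayed below the autosomal share in each.

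**Figure D3:**
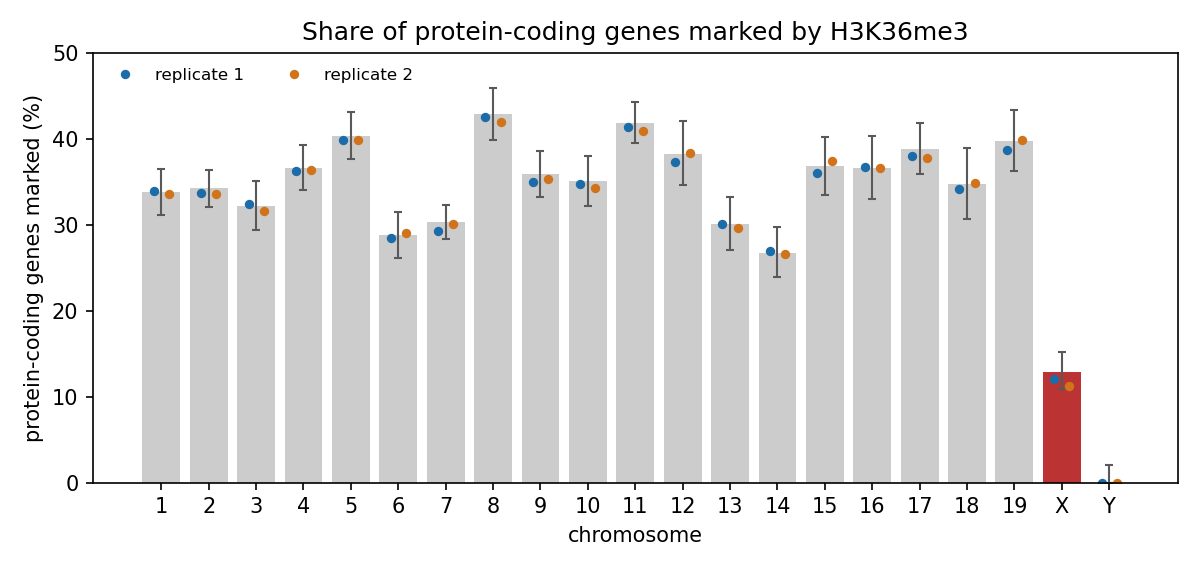
Share of protein-coding genes marked (vertical axis, percent) on each chromosome (horizontal axis) in the replicated peaks (bars, with Wilson 95% intervals over genes; X in red) and in each replicate list (points). X stands at 12.9%, below the lowest autosome at 26.7%, and Y at 0.

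Few genes differed in their call between the replicates. Of the genes marked in either replicate, 7085 were marked in both, 292 in replicate 1 only and 302 in replicate 2 only, so that 594 differed. Across genes the coverage of the replicates correlated with a Spearman rho of 0.963 and a Pearson r of 0.987; genes are not independent replicates. The median absolute difference of marked genes was 3.49 percentage points, and the 90th percentile was 9.62. The genes of 10 kb or more with the largest excess in replicate 1 were Vps29, a retromer subunit gene (53.4% against 34.0%), Wdr73 (64.9% against 46.6%) and the splicing regulator gene Rbm4b (65.9% against 49.0%). Those with the largest excess in replicate 2 were the water channel gene Aqp1 (43.5% against 20.7%), the phosphatase gene Ptpn7 (26.3% against 6.28%) and Smim11 (30.3% against 11.6%). With a single library per replicate no test of these differences exists. When any covered base counted as marked, 1143 genes differed.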

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

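The tests of single globin genes and the count of short ribosomal protein genes by family symbol were chosen only after the result was seen. The X share under both the promoter and the family filter was not set down beforehand. The other tests below were set down before their results were computed. A signal lay outside the chromosomes on which the comparisons were made: 14 replicated peaks fell on 4 scaffolds, covering 11.6 kb, with a median enrichment of 2.74 against 3.18 on the chromosomes. No control list was among the files analysed, so no background level can be set beside them.

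Fetal hepatocyte genes were marked less often than erythroid genes. Gene length as the whole cause is argued against by members of 10 kb or more, where 25 of 25 erythroid and 11 of 25 hepatocyte genes were marked, a difference of 56.0 percentage points (p = 9.51e-06, Fisher's exact test). The calling threshold stays open: when any base under the pooled list counted, 29 of 35 erythroid and 30 of 39 hepatocyte genes had a peak, a difference of 5.93 points (p = 0.575, Fisher's exact test), but either choice alone kept the excess past the test, at 34.1 points with the pooled list (adjusted p = 0.00381) and 26.4 points with any base under replicated peaks (adjusted p = 0.0227). A smaller share of hepatocytes in the tissue stays open too and may lower their enrichment. The median of the highest enrichment in the 11 marked hepatocyte genes was 3.18 against 9.73 in the 29 marked erythroid genes, a ratio of 0.327 (permutation p = 2e-05, the smallest that 100000 resamples can give), but the same peaks set which genes count as marked, so this is not independent support, and fewer transcripts per hepatocyte gene were not excluded.

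X-linked genes were marked less often than autosomal genes. Promoter class as the whole cause is argued against: among genes with a CpG-rich promoter 33.1% of X genes were marked (84 of 254, Wilson 95% interval 27.6 to 39.1), against 57.7% on the autosomes and 47.9% on the lowest autosome, although promoter class could account for part, since CpG-rich promoters belong to 26.8% of X genes and 47.2% of autosomal genes. Shared reads between copies of gene families were tested only by leaving out families of 4 or more members on a chromosome, grouped by symbol. After that, 16.3% of X genes were marked (interval 13.8 to 19.3), against 29.4% on the lowest autosome. Smaller families and copies with Gm symbols stayed in, and read uniqueness was not measured for X genes, so shared reads were not excluded. With the promoter and family filters together, 36.1% of X genes were marked (79 of 219, interval 30.0 to 42.6). The autosomal share was then 57.6%, and 47.2% on the lowest autosome. A lower enrichment on X stays open: marked X genes had a median highest enrichment of 3.88 against 5.06 on the autosomes, a ratio of 0.766 (permutation p = 2e-05, the smallest that 100000 resamples can give), but the same peaks set which genes count as marked, so this is not independent support. A single active X per cell is a biological candidate that these mixed-sex pools cannot test. The number of X copies in these pools was not allowed for here, and what the enrichment was computed against is not stated. A technical cause was therefore not separated from a biological one.

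The 6 globin genes had no replicated peak in a tissue whose other erythroid genes were heavily marked. Over the 6 genes the median share of 32-base words that occur once in the genome was 27.8%, with members on both sides of the bounds set. In Hba-a1, Hba-a2, Hbb-bs and Hbb-bt it was at most 30.0%, so reads shared between copies may explain the missing peaks there. A low share did not by itself remove every peak, as the 43.3 kb erythroid gene Slc25a37 had 28.5% and was covered over 28.9% of its body. Whether its peak lay in unique sequence was not examined. In Hba-a1 and Hba-a2 the share was lower, at 3.46% and 4.11%. In Hbb-bh1 and Hbb-y the share was 100%, which argues against shared reads for these embryonic genes. A short body was not decided: of 18 protein-coding genes of 2 kb or less with symbols that begin with Rpl or Rps, 7 were marked (38.9%, Wilson 95% interval 20.3 to 61.4), between the bounds of 10% and 50%. Without 6 pseudogene symbols and Rps27rt, 6 of 11 were marked (54.5%, interval 28.0 to 78.7), an interval that includes the upper bound; no biological explanation was tested.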

How the results depend on the processing

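The alternative with overlapping genes left out was chosen after the data had been seen; the others were planned. Of 60 recomputed list contrasts under 10 settings, 55 kept their direction and their side of the threshold. Fetal hepatocyte against neuronal genes no longer passed at 10.3 points, both at 25% coverage and with the 50% of peaks of higher enrichment. Fetal against adult hepatocyte genes passed in the pooled list (28.7 points) and when any base counted (33.1 points), and turned to -3.08 points at 25% coverage; its adjusted p ranged from 0.00872 to 1. The cause was not tested. Of 190 recomputed shares of marked list members, 126 stayed within the SD between replicates and 64 moved beyond it. The fetal hepatocyte share of 28.2% ranged from 10.3% to 56.4%. Of 486 recomputed coverage values of named genes, 161 moved beyond their SD.

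Shared peaks were 67.1% with an overlap of 50% of the shorter peak, 41.3% of both peaks, 72.2% in the 50% of peaks of higher enrichment and 63.9% with peaks less than 1 kb apart joined. The share of peak bases in gene bodies was 95.5% with the 50% of higher enrichment, 95.3% with peaks joined, 94.8% in the pooled list, 95.9% over all annotated genes and 95.03% to 95.2% with either replicate left out. The 3′ to 5′ ratio was 2.65 with the 50% of higher enrichment, 2.17 in the pooled list, 6.54 from single end bins, 2.80 with genes of 2 kb or more, 2.37 without overlapping genes and 2.30 to 2.37 with either replicate left out. The X share was 7.81% with the 50% of higher enrichment, 13.4% with peaks joined, 15.9% in the pooled list, 8.44% at 25% coverage, 21.1% at any base, 15.4% with genes of 2 kb or more, 12.1% without overlapping genes and 11.3% to 12.0% with either replicate left out; the autosomal share was 2.18 to 3.70 times it. Genes that differed between replicates numbered 1143 at any base, and the other 17 recomputed counts stayed within 1.5 times. Causes of these shifts were not tested. Leaving out a replicate gives no value for shared peaks or for genes that differ. Unknown depth limits all of these values.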

Other observations

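All groups and genes in this part were chosen after the data had been seen, so none was a planned test. Gene families named by symbol ranged from fully marked to unmarked. All 9 Mcm genes, Mcm2 to Mcm10, were marked (median coverage 87.0%), as were 50 of 55 Eif translation initiation genes (90.9%), 75 of 83 Rpl and Rps ribosomal protein genes, without pseudogene symbols (90.4%, median coverage 63.2%), 27 of 29 Polr RNA polymerase genes (93.1%), 41 of 46 Nduf genes of respiratory complex I (89.1%) and 34 of 39 Psm proteasome genes (87.2%). Families in between were the Usp deubiquitinase genes (36 of 56, 64.3%), Cdk kinase genes (11 of 18, 61.1%) and Zfp zinc finger genes (222 of 394, 56.3%). So were the Kif kinesin genes (20 of 39, 51.3%), Slc solute carrier genes (124 of 371, 33.4%) and Serpin genes (6 of 61, 9.84%). Of 35 genes matched by an Apo symbol pattern, which is not limited to apolipoproteins, 6 were marked (17.1%). At the other end, none of 53 Krt keratin genes, 1 of 1135 Olfr olfactory receptor genes, 0 of 331 Vmn vomeronasal receptor genes, 0 of 39 Hox genes and 3 of 100 Cyp cytochrome P450 genes (3.00%) were marked. Hist genes, whose replication-dependent transcripts lack a poly(A) tail, were marked in 2 of 67 cases (2.99%), Hist1h2bc and Hist3h2a, although cell cycle genes carried the highest coverage of all lists; 58 of the 67 are no longer than 2 kb.

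In 6 classes of non-coding genes and pseudogenes, the marked members were compared with marked protein-coding genes. The share that overlapped such a gene was 92.4% of 66 sense intronic, 91.9% of 494 antisense, 85.6% of 257 small nucleolar RNA, 85.5% of 346 microRNA, 81.5% of 297 processed pseudogene and 56.1% of 157 long intergenic RNA genes; other classes were not tested. Away from marked protein-coding genes, 69 of 5673 long intergenic RNA genes (1.22%) and 40 of 2098 antisense genes (1.91%) were marked. Among long intergenic RNA genes of at least 2 kb with no protein-coding gene within 5 kb, 19 were marked. The highest were Mir17hg, the host of the miR-17 cluster (mm10 chromosome 14, 115042879 to 115046727, 81.0% ± 2.66, SD, n = 2), and Malat1 (chromosome 19, 5795690 to 5802672, 70.5% ± 0.729); Redrum had 30.8% ± 5.44 and Ftx, an X-linked RNA gene near Xist, 25.8% ± 1.53. Of 31504 domains formed by joining replicated peaks less than 1 kb apart, 46 (0.146%) lay 10 kb or more from every annotated gene. Among the 52 marked protein-coding genes of 200 kb or more was Sox6, a transcription factor gene of red cell development (568 kb, 12.9% ± 0.463), with an enrichment of up to 7.35.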
